A study of Bos taurus with 4 samples.

How the data were processed

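The data were 4 two-colour oligonucleotide arrays of the bovine EmbryoGENE design, 1 for each of 4 Holstein heifers, and each array held the early blastocyst pools of 1 heifer at donor ages of 11 and 14 months. Per the labels' protocols, heifers were stimulated with FSH, oocytes were matured, fertilized and cultured in vitro, and total RNA was extracted from pools of embryos. Per the same protocols, the RNA was amplified linearly in 2 rounds and labelled with Cy3 or Cy5 by a chemical kit. Amplification can change the relation between transcripts, and a ratio compares 2 pools prepared by the same protocol. The oocytes of a heifer at the 2 ages were collected at different times, so that the time of collection cannot be told apart from donor age. Groups and dyes were taken from the source names of the 2 channels, and replicate numbers from the descriptions; titles name a different heifer for each array.

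The deposited scanner files give, per the file headers, the intensity of each spot and of its local background in both channels as a mean and as a median on a linear scale, not background-corrected. The authors also deposited a table of normalized log2 ratios and a series matrix with log2 ratios; their normalization method, image software and scanner are not given in the sources used here. Set against the scanner values, the deposited log2 table ran Cy5 over Cy3 on all 4 arrays, and the matrix held the same values within 5e-06 with the sign turned on replicates 3 and 4, so that all ran 11 over 14 months. Its correlation across probes with background-subtracted, loess-normalized ratios of the same array was 0.986 to 0.993, with slopes of 0.884 to 1.08, from which base 2 was taken. The medians of the matrix columns were 0.00853, 0.00336, 0.00104 and 0.0234. The authors' centring and background method stay unknown.

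Analyses were run in R 4.3.3 with limma 3.58.1, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Median foreground signals were corrected with the median local background by normexp with an offset of 50, and log2 ratios were normalized within each array by loess, in which the 1426 control and blank spots had weight 0. Medians were used in place of means because the deposited log2 ratios lay closest to those made from medians. Ratios were turned to 11 over 14 months by the dyes in the labels. Probes were kept whose mean log2 intensity over the 4 arrays was above the mean plus 2 SD of 153 negative control spots, which left out 7347 of 43794. The same limit, set per channel and array, gave the share of probes above background and the number of arrays on which a named gene was detected.

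Gene names came from GEO's platform annotation. It gives 1 symbol for 21790 probes, several for 0 and none for 22004, and the last are unnamed here. Of the named probes, 20068 symbols matched a current symbol of the ARS-UCD2.0 reference table, 1646 were updated through a synonym and 76 matched neither and kept their old name. No genome build is given for the array design in the sources used here, so that no coordinates are printed.

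The log2 ratios were fitted with lmFit and eBayes with 1 coefficient, the mean over the 4 heifers, and tested two-sided with Benjamini-Hochberg adjustment over all 36447 probes. The ratio within an array already pairs the ages of a heifer, and a dye effect of a probe cancels in the mean, since each orientation was used on 2 arrays. Such an effect stays in the SDs over heifers and in the residual variance of this fit, which has no dye term. The dye orientation was the technical batch, and the slide was not, since all 4 arrays appear to share 1 slide. The residual degrees of freedom were 3, with 3.71 prior degrees of freedom. An exact sign-flip test of 4 paired values cannot give a two-sided p below 0.125. The spread of single values is given as the SD over heifers.

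The rule for named genes, fixed before the data were examined with the gene lists, the tests and the alternatives, took up to 12 genes in each direction. Genes past an adjusted p of 0.05 came first, and the remaining places went to those of at least 1.5-fold and 1 sign on all 4 arrays, by the smallest unadjusted p. It further took the 3 members of each list with the smallest unadjusted p, XIST and the Y-linked genes. A gene with several probes was named by its probe with the highest mean signal, and an opposite sign of another of its probes at an unadjusted p under 0.05 was stated. Gene lists with at least 5 measured members were tested on 1 probe per gene with camera at an inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. Of the 29 lists, the mitochondrially encoded transcripts had no measured member and the X inactivation centre held XIST alone.

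The scripts were tested on simulated arrays made from the real mean signals, the probe variances after limma's moderation and part of the orientation effect. Noise was independent between arrays and between probes. In this simulation of the age comparison over 36408 probes, the fit recovered 66 of 66 probes changed 4-fold, 62 of 67 changed 2-fold and 20 of 67 changed 1.5-fold at an adjusted p of 0.05, and called 2 of 36077 unchanged probes. Camera called each of 3 lists shifted by 0.1, 0.2 and -0.3 on the log2 scale and 0 of 24 unshifted lists. The simulation leaves out noise shared by arrays and noise correlated between genes, and its variances were already moderated. Its recovery rates therefore need not hold for the real arrays.

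The alternatives were no background correction, plain subtraction with non-positive signals left out, a normexp offset of 16, median centring, loess followed by Aquantile scaling, no filter and a stricter filter on dim probes, a gene-specific dye term, array weights, eBayes with trend and robust, mean foreground signals, both deposited tables, a separate-channel fit without the array as a block, and each replicate left out in turn. For gene lists, the mean of a gene's probes was tried as well.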

Results

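Messenger RNA was measured in pools of early blastocysts, the stage at which the bovine embryo forms a fluid-filled cavity and its outer trophectoderm separates from the inner cell mass. The embryos were produced in vitro from oocytes of Holstein heifers (Bos taurus) and collected 168 hours after in vitro fertilization. Each of the 4 two-colour arrays held both pools of 1 heifer, one from oocytes collected at a donor age of 11 months and the other from oocytes of the same heifer at 14 months. The 4 replicates were different heifers, so that the spread between arrays includes differences between animals and between the 2 dye orientations given next. The 11-month pool carried the dye Cy5 in replicates 1 and 2 and the dye Cy3 in replicates 3 and 4. The number of embryos in a pool is not given in the sources used here. According to the series title, the study addressed the quality of embryos from donors around puberty, and the comparison asked which transcripts differed between the pools of the 2 donor ages. All ratios below are log2 of 11 over 14 months, so that a positive value is a higher signal in embryos of the younger donor, and errors are SDs over the 4 heifers.

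Of 43794 probes for bovine transcripts, 36447 had a mean signal above the negative control spots and were tested; 18723 of these carried a gene symbol, for 13516 genes. In the 11-month pools, 65.2%, 73.0%, 64.5% and 68.2% of all probes lay above the negative controls in replicates 1 to 4, against 62.6%, 65.6%, 74.1% and 75.9% in the 14-month pools. On each of the 4 arrays the larger share was in the Cy5 channel. No spot reached the 16-bit limit of 65535, the brightest being at 59161. The number of arrays, 4, limits the precision of every value.

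Of the genes named by the rule below, those with the smallest unadjusted p, none of them past the adjusted threshold, were NANOG, higher in the pools from 11-month donors by 1.10 ± 0.42 (SD, n = 4) or 2.14-fold, and PHGDH and SLC7A5, lower at -0.87 ± 0.29 and -0.83 ± 0.28. NANOG is a transcription factor of pluripotent inner cell mass cells, PHGDH the first enzyme of serine synthesis and SLC7A5 a transporter of large neutral amino acids. Each of the 3 genes had the same sign in all 4 heifers, as the rule required. No probe passed an adjusted p of 0.05 with limma's moderated test and Benjamini-Hochberg adjustment, and the lowest adjusted p was 0.388. At an unadjusted p under 0.05 there were 3448 probes, 1348 higher and 2100 lower in the 11-month pools. Chance alone would give 1822 with independent arrays. Taken as Cy5 over Cy3 on all 4 arrays, the same ratios gave 5153 such probes, so that the excess alone is no sign of an age difference. The median absolute log2 ratio over all tested probes was 0.09, and the median SD between heifers was 0.21.

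With a change of at least 1.5-fold and an unadjusted p under 0.05, a list that carries no claim of significance, there were 501 probes, 201 higher and 300 lower in the 11-month pools, so that 40.1% were higher. With median centring in place of loess the split was 114 higher and 283 lower, or 28.7% higher. Counted by the brightest probe of each gene the balance was the other way, with 100 genes higher and 65 lower; 199 of the 501 probes carried a gene symbol. In 122 of the 501 probes the change was at least 1.5-fold both in the mean of replicates 1 and 2 and in the mean of replicates 3 and 4, and 370 had the same sign on all 4 arrays. Such agreement is favoured by choosing the list on these arrays, and over all tested probes the same pair of means correlated at r = -0.08. The list held 156 probes without replicate 2 and 1110 without replicate 4. Its split was 347 higher and 250 lower without replicate 1, and 99 higher and 600 lower without replicate 3.

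In each direction 12 genes were named by the smallest unadjusted p among those of at least 1.5-fold with 1 sign in all 4 heifers, and none of these 24 passed the adjusted threshold. Besides NANOG, the genes higher in the 11-month pools were LIX1 at 0.98 ± 0.67, B2M at 0.80 ± 0.45, NUCB2 at 0.80 ± 0.47, BIN2 at 0.79 ± 0.30, HEBP2 at 0.64 ± 0.35, TM4SF1 at 0.63 ± 0.32, ENO1 at 0.61 ± 0.19, NID1 at 0.61 ± 0.14, ATXN7L3 at 0.60 ± 0.35, SEPTIN10 at 0.59 ± 0.32 and LOC100295873 at 0.59 ± 0.32. B2M is the invariant light chain of MHC class I molecules, ENO1 the glycolytic enzyme enolase and NID1 the basement membrane protein nidogen. Besides PHGDH and SLC7A5, the genes lower in the 11-month pools were LOC509782 at -1.72 ± 0.84, SLC35G1 at -1.08 ± 0.42, LOC522428 at -0.99 ± 0.42, LOC513925 at -0.96 ± 0.38, LOC100295855 at -0.91 ± 0.38, NCEH1 at -0.83 ± 0.33, SERPINB2 at -0.72 ± 0.23, TTC4 at -0.67 ± 0.20, DTX3 at -0.64 ± 0.20 and RDH13 at -0.59 ± 0.19. NCEH1 hydrolyses cholesteryl esters, SERPINB2 inhibits plasminogen activators and RDH13 is a retinol dehydrogenase. LOC509782, lower by 3.29-fold, had the largest change of the 24, and it spanned -2.62 to -0.68 among heifers. The reference annotation lists LOC509782, LOC513925, LOC100295855 and LOC100295873 as pseudogenes, and their values are uncertain, since such a probe can read a related transcript. A second probe of SLC35G1 had the opposite sign, at 0.48 ± 0.36, so that the direction for this gene is not settled. Dimmer probes of NCEH1 at 0.11 ± 0.40 and 0.18 ± 0.22, of B2M at -0.19 ± 0.15, of HEBP2 at -0.17 ± 0.16 and of ATXN7L3 at -0.13 ± 0.07 also had the opposite sign, none at an unadjusted p under 0.05. Of the 100 genes named by rule here and in the gene lists below, 41 had several tested probes, and 14 of these had a probe of the other sign, the remaining ones being RPL21, DAB2, SPP1, NR5A2, ATP5MC1, HMGCS1, RPA2, TDG and IMPACT.

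**Figure D1:**
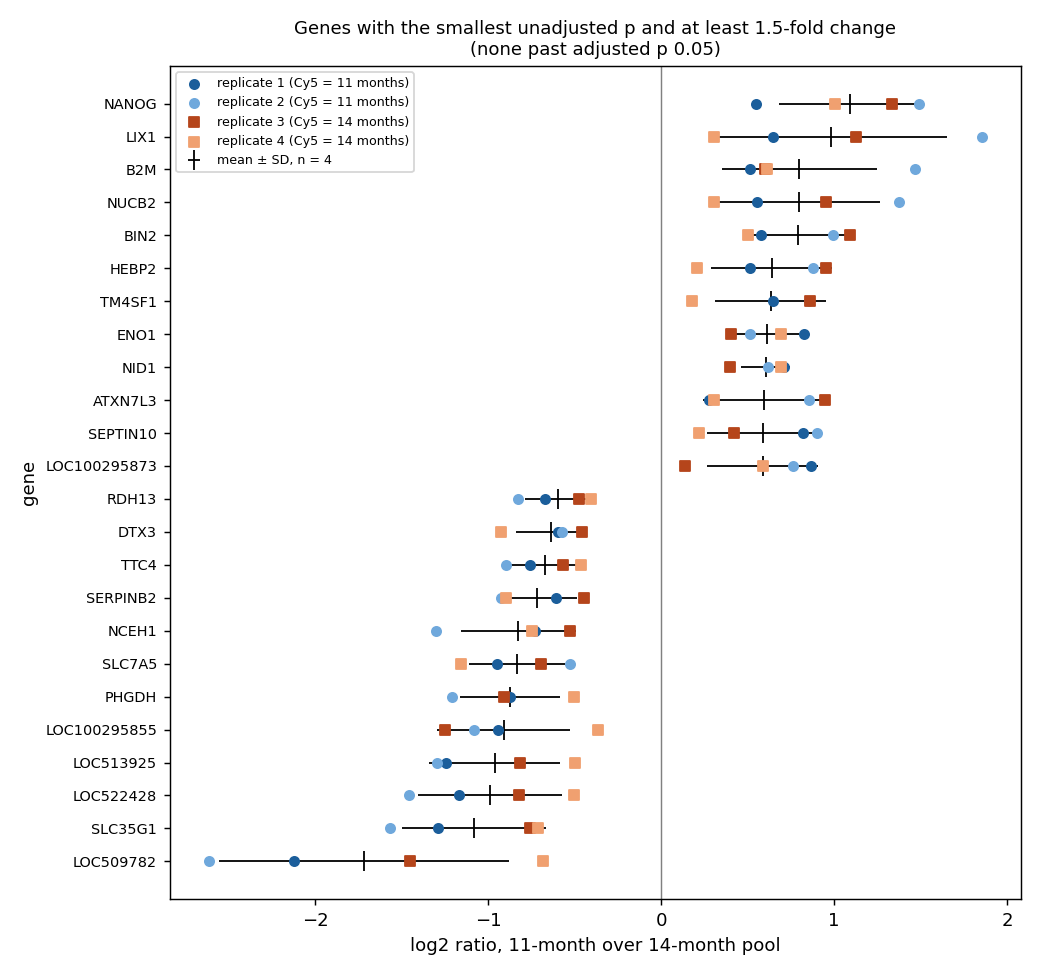
Log2 ratio of the 11-month over the 14-month pool (x axis) for the 24 named genes (y axis). Points are the 4 heifers, circles with Cy5 on the 11-month pool and squares with Cy5 on the 14-month pool, and bars are the mean ± SD; NANOG lies at 0.55 to 1.49 and PHGDH at -1.21 to -0.51 in the 4 heifers, and no gene passed an adjusted p of 0.05.

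The arrays of one dye orientation resembled each other more than they resembled arrays of the other orientation. Across the 36447 tested probes, which are not independent replicates, the log2 ratios turned to 11 over 14 months correlated at r = 0.58 between replicates 1 and 2 and at r = 0.28 between replicates 3 and 4. The 4 pairs of opposite orientation gave r = -0.18, -0.17, 0.14 and -0.07. All 4 arrays had 1 sign in 16.7% of probes, against 12.5% by chance if the arrays were independent. Taken as Cy5 over Cy3 on all 4 arrays, the ratios had 1 sign in 24.95% of probes, so that more probes followed the dye orientation than age. Fitted alone, replicates 1 and 2 gave 2886 probes past an adjusted p of 0.05 in limma, and replicates 3 and 4 gave 0, with 4131 at an unadjusted p under 0.05. In each of these fits of 2 arrays, age and dye cannot be told apart, so that the counts are not counts of age differences. With a gene-specific dye term in the fit of all 4 arrays, 0 probes passed for age, with a lowest adjusted p of 0.0522, and 513 passed for the orientation term, which the heifers of replicates 1 and 2 share against those of replicates 3 and 4.

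Of 29 gene lists fixed before the data were examined, 27 had at least 5 measured members. None of the 27 passed an adjusted p of 0.05 in camera, which compares a list with all other genes; the lowest adjusted p was 0.498, or 0.770 with an estimated correlation, and 1 list had an unadjusted p under 0.05. In fry, which asks whether a list moves on balance one way, 0 passed, with a lowest adjusted p of 0.149 and 3 lists at an unadjusted p under 0.05. No list member passed over all probes, while 10 memberships in 5 lists had p under 0.05 adjusted over the list alone. Without replicate 3, cholesterol biosynthesis passed in camera, with an adjusted p of 0.0124 and a median of 0.17. Without replicate 4, the developmental competence markers passed, at 0.0432 and a median of 0.12, and neither passed with an estimated correlation.

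**Figure D2:**
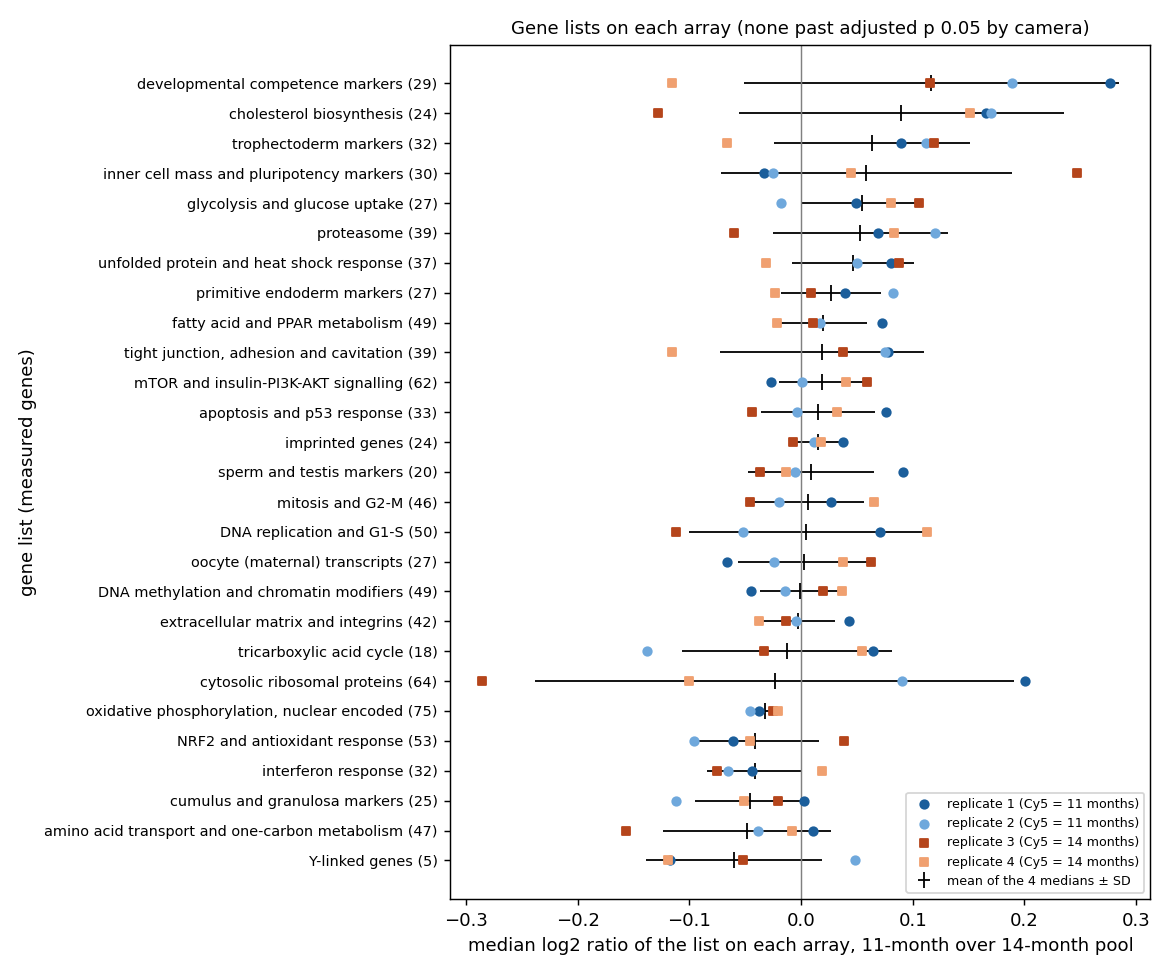
Median log2 ratio of each of the 27 gene lists on each array (x axis), with the number of measured genes in brackets (y axis). Points are the 4 heifers, marked by dye orientation, and bars are the mean of the 4 medians ± SD; the ribosomal proteins lie at 0.20 and 0.09 in replicates 1 and 2 and at -0.29 and -0.10 in replicates 3 and 4.

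Amino acid transport and one-carbon metabolism had members at both ends of the range. Of 47 measured genes, 4 were higher and 8 lower at an unadjusted p under 0.05, and 4 had p under 0.05 adjusted over the list alone: PHGDH, SLC7A5 and SLC1A4, lower, and ODC1, higher. SLC1A4, a transporter of alanine, serine and cysteine, was at -1.05 ± 0.62. ODC1, the first enzyme of polyamine synthesis, was at 0.42 ± 0.14, and was named after its values were seen. The list passed fry's mixed test, which asks whether genes differ in either direction, at an adjusted p of 0.0105, and its median was -0.01 with a camera adjusted p of 0.498. With the interferon response it was 1 of 2 lists past the mixed test; the count was 0 with median centring, without the array as a block, or without replicate 1, 3 or 4. It was 1, the amino acid list, with background subtraction, no filter on dim probes or mean foreground signals, 3 with no background correction, where the oocyte transcripts passed too, and 13 with a gene-specific dye term.

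**Figure D3:**
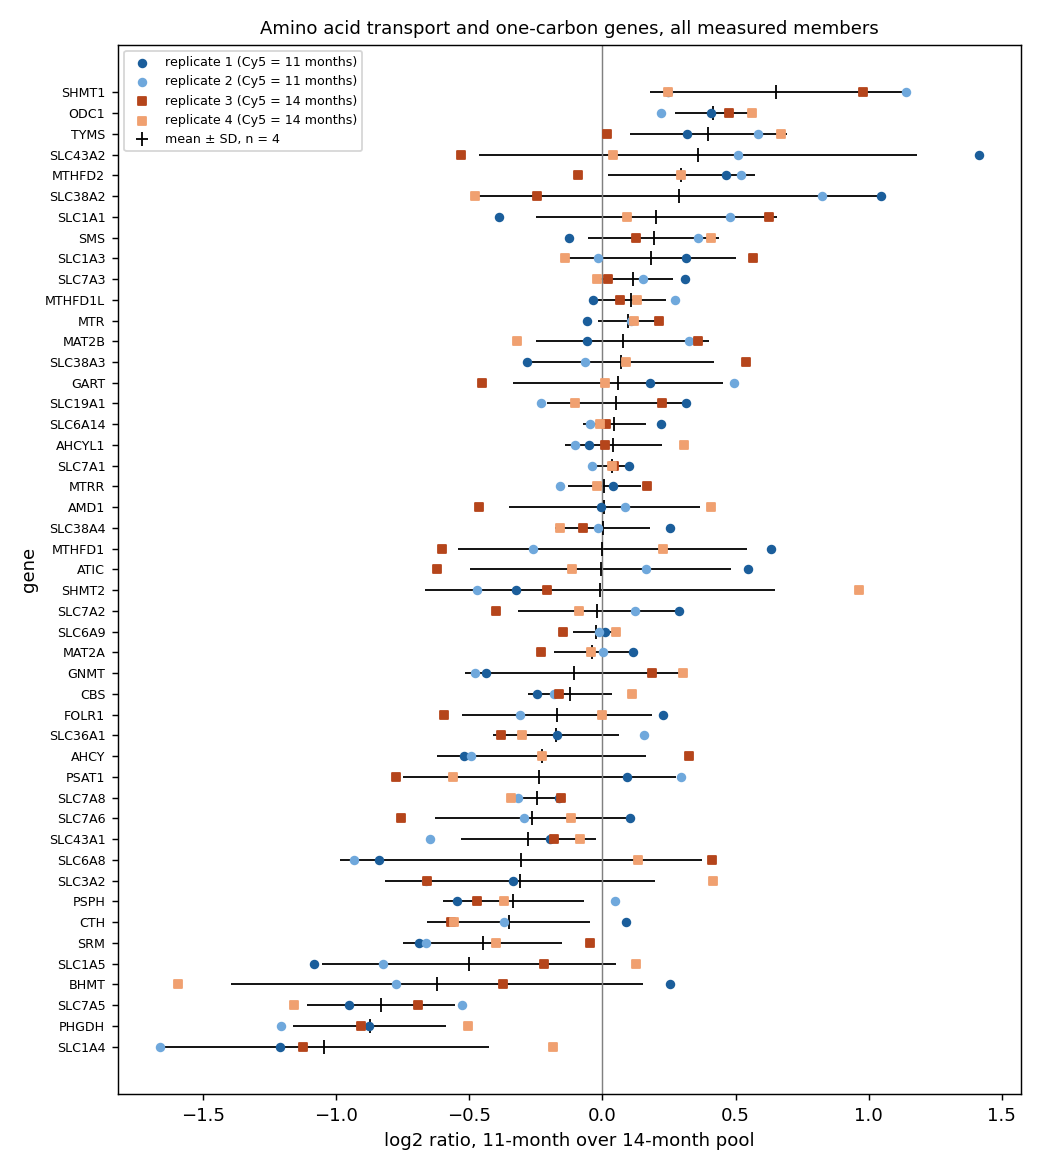
Log2 ratio of the 11-month over the 14-month pool (x axis) for the 47 measured genes of amino acid transport and one-carbon metabolism (y axis). Points are the 4 heifers, marked by dye orientation, and bars are the mean ± SD; SLC1A4 at -1.05, PHGDH at -0.87 and SLC7A5 at -0.83 stand lowest, and the SDs of most other members cross 0.

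None of the lists of embryonic lineages passed the adjusted threshold. Among 30 inner cell mass and pluripotency markers, 2 were higher and 1 lower at an unadjusted p under 0.05: NANOG, NR5A2 at 0.59 ± 0.59 and SPP1 at -0.41 ± 0.11, and NANOG and SPP1 had p under 0.05 adjusted over the list alone. The list's median was 0.03, with a camera adjusted p of 0.508. The means of the array medians were -0.03 in replicates 1 and 2 and 0.15 in replicates 3 and 4. Of 32 trophectoderm markers 4 were higher and 2 lower, with a median of 0.05, or 0.03 to 0.18 without 1 replicate, and an adjusted p of 0.508. They included the water channel AQP3 at 0.60 ± 0.38, the proton pump subunit ATP12A at 0.52 ± 0.21 and the endocytic adaptor DAB2 at -0.49 ± 0.27. The means of this list's array medians were 0.10 in replicates 1 and 2 and 0.03 in replicates 3 and 4. KRT8, named after its values were seen, was at -0.16 ± 1.65. It was at 1.37 and 1.15 in replicates 1 and 2, and at -1.57 and -1.61 in replicates 3 and 4. Of 27 primitive endoderm markers 1 was higher and 1 lower, with a median of 0.01 and an adjusted p of 0.911; CTSV was at 0.54 ± 0.48, GATA4 at -0.31 ± 0.26 and RBP4 at -0.18 ± 0.16. The 39 genes of tight junctions, adhesion and cavitation had 6 higher and 2 lower, a median of 0.02 and an adjusted p of 0.572. Among them were CTNNB1, the beta-catenin of cell junctions, at 0.64 ± 0.40 and the tight junction protein CLDN3 at -0.71 ± 0.66. Of 42 extracellular matrix and integrin genes 2 were higher and 3 lower, with a median of 0.00 and an adjusted p of 0.911; NID1 alone had p under 0.05 adjusted over the list alone, and the fibronectin receptor subunit ITGA5 was at -0.43 ± 0.29.

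Nor did any list of transcripts from other cells that a pool could carry, or the list of maternal transcripts of the oocyte. The 25 cumulus and granulosa markers had a median of -0.04 and a camera adjusted p of 0.508, with 1 lower at an unadjusted p under 0.05. In fry this list, with 16 of 25 genes lower, had the lowest adjusted p of the 27, the 0.149 given above. In this list GATM was at -0.33 ± 0.17, from a probe well above background at 11 months on 2 of the 4 arrays, and FDX1 at 0.41 ± 0.49. VCAN, at -0.22 ± 0.15, was not well above background at 11 months on any array and was above it at 14 months on 3. From the mean signals this gives a bound of 1.04-fold higher at 14 months. The 20 sperm and testis markers had a median of 0.03 and an adjusted p of 0.911; PGK2 was at 0.12 ± 0.14 and SPATA18 at 0.12 ± 0.21. CATSPER1, a sperm calcium channel subunit, was at -0.27 ± 0.11. It was likewise not well above background at 11 months, with a bound of 1.05-fold higher at 14 months. Such bounds were taken from the mean signals of each channel after loess and between-array scaling. They come from probes near background and are not guaranteed minima. In limma the adjusted p was 0.532 for VCAN and 0.44 for CATSPER1. The 27 oocyte transcripts had a median of -0.03 and an adjusted p of 0.886, with NLRP5 at -0.30 ± 0.16, CPEB1 at -0.26 ± 0.24 and FIGLA at 0.22 ± 0.20. At 11 months NLRP5 was well above background on 1 of the 4 arrays and CPEB1 on 2, so that their ratios are uncertain.

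The sex of the embryos in the pools is not given in the sources used here. XIST, the RNA that silences 1 X chromosome in female cells, was at -0.23 ± 0.48, with 0.17 and 0.20 in replicates 1 and 2 and -0.55 and -0.73 in replicates 3 and 4. The 5 measured Y-linked genes had a median of -0.08 and a camera adjusted p of 0.508. DDX3Y was at -0.17 ± 0.31, ZFY at -0.09 ± 0.17, SRY at -0.08 ± 0.18 and EIF1AY at 0.01 ± 0.19, and TSPY was not well above background at either age. At 11 months ZFY and EIF1AY were well above background on 1 of the 4 arrays, and SRY and XIST on 2; at 14 months EIF1AY was on 2, ZFY on 3 and SRY and XIST on 4. The ratios of these 4 genes are therefore uncertain.

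In energy metabolism, glycolysis and glucose uptake had 3 of 27 genes higher and 0 lower at an unadjusted p under 0.05, with a median of 0.05 and a camera adjusted p of 0.498. ENO1 had p under 0.05 adjusted over the list alone; the monocarboxylate transporter SLC16A1 was at 0.36 ± 0.26 and PFKFB3, which makes an activator of phosphofructokinase, at 0.26 ± 0.21. Of 75 nuclear-encoded genes of oxidative phosphorylation 6 were higher and 7 lower, with a median of -0.04 and an adjusted p of 0.498. The array medians of this list lay between -0.05 and -0.02 in all 4 heifers. Its members SDHB, a subunit of succinate dehydrogenase, NDUFA11 of complex I and ATP5MC1 of the ATP synthase were at -0.59 ± 0.27, -0.75 ± 0.68 and -0.31 ± 0.14. In the tricarboxylic acid cycle, 1 of 18 genes was lower, the mitochondrial PEP carboxykinase PCK2 at -0.48 ± 0.41; DLD was at 0.21 ± 0.21 and CS at 0.19 ± 0.26. Without 1 replicate PCK2 was at -0.58 to -0.28, DLD at 0.11 to 0.26 and CS at 0.11 to 0.31, and the list had a median of -0.02 and an adjusted p of 0.662. Cholesterol biosynthesis had 4 of 24 genes higher and 1 lower, a median of 0.09 and an adjusted p of 0.498, with HMGCS1 at 0.44 ± 0.34, PMVK at 0.36 ± 0.24 and SCAP, the escort protein of the sterol-responsive SREBP factors, at -0.27 ± 0.11. Fatty acid and PPAR metabolism had 2 of 49 higher and 0 lower, a median of 0.03 and an adjusted p of 0.508; ACADM was at 0.43 ± 0.29, ELOVL5 at 0.29 ± 0.07 and HADHB at 0.22 ± 0.15. Of 53 genes of the NRF2 and antioxidant response 3 were higher and 4 lower, with a median of -0.06 and an adjusted p of 0.508, and PRDX3, GPX2 and TKT were at -0.40 ± 0.22, -0.36 ± 0.14 and -0.34 ± 0.21. Of 62 genes of mTOR and insulin signalling 4 were higher and 3 lower, with a median of -0.03 and an adjusted p of 0.911; the translation factors EIF4A1 and EIF4B were at -0.46 ± 0.33 and 0.24 ± 0.06, and EEF2K at 0.34 ± 0.26. EIF4B was at -0.01 when mean foreground signals were used.

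None of the lists of protein synthesis and folding passed the adjusted threshold. Of 64 cytosolic ribosomal protein genes 1 was higher and 6 lower at an unadjusted p under 0.05, with a median of -0.02 and a camera adjusted p of 0.498. The means of the array medians were 0.15 in replicates 1 and 2 and -0.19 in replicates 3 and 4. RPS7 was at -0.49 ± 0.18, RPLP2 at -0.35 ± 0.18 and RPL21 at -0.43 ± 0.26, and another probe of RPL21 had the opposite sign at 0.37 ± 0.11, so that its direction is not settled. Values of ribosomal protein genes are uncertain, since probes can read their many processed copies. Of 39 proteasome genes 5 were higher and 3 lower, with a median of 0.05 and an adjusted p of 0.498; PSMA4 was at 0.45 ± 0.42, PSMB7 at 0.30 ± 0.21 and the immunoproteasome subunit PSMB10 at -0.36 ± 0.13. The unfolded protein and heat shock response had 6 of 37 genes higher and 4 lower, a median of 0.13, a mean of 0.04 and an adjusted p of 0.508. Its chaperones of the endoplasmic reticulum HSP90B1 and HSPA5 were at 0.49 ± 0.44 and 0.46 ± 0.32, whereas ASNS, the asparagine synthetase, was at -0.63 ± 0.40.

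In the cell cycle, DNA replication and G1-S had 4 of 50 genes higher and 5 lower at an unadjusted p under 0.05, with a median of -0.02 and a camera adjusted p of 0.911. RFC3 was at 0.37 ± 0.18 and RPA2 at 0.31 ± 0.02, and the cyclin CCND3 was at -0.28 ± 0.09. Mitosis and G2-M had 2 of 46 higher and 4 lower, a median of 0.02 against a mean of -0.01 and a downward direction in camera, and an adjusted p of 0.911; NUSAP1 was at 0.39 ± 0.30, the checkpoint protein MAD2L1 at 0.35 ± 0.14 and DLGAP5 at -0.34 ± 0.07. The 33 genes of apoptosis and the p53 response had 2 higher and 0 lower, a median of 0.00 and an adjusted p of 0.572. The p53 targets TP53I3 and CDKN1A were at 0.43 ± 0.09 and 0.22 ± 0.09, and the apoptosis inhibitor BIRC3 at -0.21 ± 0.16.

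Of 32 interferon response genes 3 were higher and 6 lower at an unadjusted p under 0.05, and the list passed fry's mixed test at an adjusted p of 0.0349, a call lost under the settings that gave 0 such lists and also with background subtraction, no filter on dim probes or mean foreground signals. Its median was -0.05 and its camera adjusted p 0.508. B2M, higher, and the antiviral membrane protein IFITM3, at -0.48 ± 0.18, had p under 0.05 adjusted over the list alone, and IRF9, a subunit of the interferon-activated transcription factor complex, was at -0.32 ± 0.15, from a probe well above background at 11 months on 2 of the 4 arrays. Of 49 DNA methylation and chromatin modifiers 7 were higher and 4 lower, with a median of 0.02 and an adjusted p of 0.911; SMARCA2 was at 0.59 ± 0.48, the DNA glycosylase TDG at 0.51 ± 0.38 and the deacetylase SIRT1 at 0.33 ± 0.21. Of 24 imprinted genes 0 were higher and 1 lower, with a median of 0.02, a mean of -0.01, an upward direction in camera and an adjusted p of 0.961; SGCE was at -0.49 ± 0.19, ASCL2 at 0.16 ± 0.24 and IMPACT at 0.18 ± 0.32. The developmental competence markers, chosen from general knowledge of bovine blastocysts, had the smallest camera p of the 27 lists, with 21 of 29 genes higher, a median of 0.11 and an adjusted p of 0.498. Only AKR1B1, at 0.37 ± 0.36, had an unadjusted p under 0.05; TXN was at 0.25 ± 0.24 and the trophectoderm factor CDX2 at 0.22 ± 0.18. The array medians of this list were 0.28 and 0.19 in replicates 1 and 2, and 0.12 and -0.12 in replicates 3 and 4.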

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

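Of 134 sets of 4 values (named genes, gene lists and array signals), 7 had 1 heifer far from the other 3 by Dixon's ratio, and chance would give about 7. The log2 ratio of B2M was 1.47 in replicate 2 against 0.51 to 0.61 in the other heifers. That of the trophectoderm marker ATP12A was 0.84 in replicate 3 against 0.39 to 0.43. EIF4B stood at 0.155 in replicate 1 against 0.26 to 0.28, and CDKN1A at 0.35 in replicate 4 against 0.16 to 0.18. AKR1B1 was at -0.17 in replicate 4 against 0.48 to 0.60 in the others. The median of the trophectoderm markers was -0.0663 in replicate 4 against 0.09 to 0.12, and that of cholesterol biosynthesis was -0.13 in replicate 3 against 0.15 to 0.17.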

How the results depend on the processing

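No probe passed an adjusted p of 0.05 under any of the 18 alternatives, with lowest adjusted p values from 0.0522 with a gene-specific dye term to 1.00 without replicate 2. The list of at least 1.5-fold at an unadjusted p under 0.05 held 851 probes (576 lower in the 11-month pools) with the lower normexp offset, 278 (124 higher and 154 lower) with mean foreground signals and 319 (36 higher) in separate channels with no replicate block. Its lower part was 482 with background subtraction and its higher part 114 with median centring. The causes were not tested, apart from the offset, which by its construction pulls the ratios of dim probes less towards 0. In the other settings with 4 arrays the total was within 1.5 times of 501. Leaving out each replicate in turn, which also unbalances the dye orientations, gave 156 to 1110 probes, 27 to 471 higher and 129 to 639 lower. It gave 0 to 1 lists in camera, and the other settings, with an estimated correlation or fry included, gave 0. The fit without the array as a block called 0 probes and 0 lists too.

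The 24 genes named by unadjusted p among those of at least 1.5-fold kept their sign in all 432 values under the alternatives. Much of this was fixed by the rule that required 1 sign on all 4 arrays, and it does not show stability. Of 1352 values of the other named genes, 9 had the opposite sign, and the cause was not tested. EIF1AY, at 0.01, was at -0.0213 with no background correction, -0.0314 with background subtraction, -0.0148 with array weights and -0.0266 with either deposited table, and between -0.0795 and 0.0587 without 1 replicate. With mean foreground signals SRY was at 0.0328 and EIF4B at -0.0119, and TSPY was between -0.127 and 0.0309 without 1 replicate. Without 1 replicate, 18 of the 100 named genes and all 27 list medians moved by over 1.5 times or turned in at least 1 of the 4 fits, in 32 of 400 and 76 of 108 values. Of 511 list medians, 483 moved by less than the SD of the array medians and 28 by more. Arrays of one orientation correlated at 0.42 to 0.44 on average and those of opposite orientation at -0.18 to -0.08 in the 3 alternatives tried. Signal over background limits the dim probes, whose ratios shrink towards 0 with a larger offset.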

Other observations

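The tests of ATF4 targets other than dye bias, of background noise, of the amino acid list against random lists and of sign patterns were set before their results were seen. The tests of dye bias, shared age difference, heifer pairs, inner cell mass share and the amino acid list as the smallest of all lists were chosen afterwards.

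PHGDH, SLC7A5, SLC1A4 and ASNS, all lower in the 11-month pools, are known targets of ATF4, the transcription factor of the response to amino acid shortage and endoplasmic reticulum stress. A list of other ATF4 targets was therefore written after PHGDH and SLC7A5 had been seen. Of its 39 measured genes, 23 of them also in the lists fixed earlier, 31 were lower in the 11-month pools, 11 of them at an unadjusted p under 0.05, against 1 higher at that level. Among its members, PYCR1 was at -0.51 ± 0.17, ATF4 itself at -0.47 ± 0.46, MARS1 at -0.40 ± 0.27, CHAC1 at -0.92 ± 1.07 and TRIB3 at -0.30 ± 0.37, whereas MTHFD2 was at 0.30 ± 0.28 and SLC38A2 at 0.29 ± 0.76. The array medians were -0.13, -0.28 and -0.24 in replicates 1 to 3 and 0.04 in replicate 4.

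A candidate explanation for the lower PHGDH and SLC7A5 is a weaker ATF4 response in the 11-month pools. The 39 other targets were lower as a set, with a median of -0.12, or -0.204 to -0.0923 over the alternatives. Without ASNS and SLC1A4, whose values had been seen, the camera p was 0.000236. Since 23 of the 39 were also in the lists fixed earlier, leaving out these genes does not make the test independent of those lists. For all 39, the camera p was 2.12e-05 at the preset correlation, and from 2.84e-07 to 0.00118 over the alternatives. With an estimated correlation, of 0.126, the p was 0.129, and fry gave 0.0909, so that the result rests on treating the genes as nearly independent; of the 8 sign patterns of the arrays, 1 other gave a smaller p, 2.57e-06. Dye bias of the 2 probes was not tested by their values, the highest of which was -0.505, since the naming rule required 1 sign on all arrays; a constant bias cancels in the mean over the balanced orientations. The amino acid list had the smallest mixed p of the 27 lists, which 0.2% of 1000 random lists of its size and brightness reached, but the smallest over random versions of all 27 was as small in 5.9% of 1000 draws, so that chance selection among lists stays open, as do donor age, embryo growth at collection and the handling of pools.

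NANOG was higher in all 4 heifers. A larger share of inner cell mass cells would raise other markers restricted to that lineage by about as much. The median of the 29 others, not all of them restricted to it, was 0.0327, with a 75th percentile of 0.11, against 1.10 for NANOG. SOX2, named after its values were seen, was at -0.33 ± 0.72 and POU5F1 at 0.04 ± 0.20. Markers that trophectoderm still expresses at this stage would move less, as would dim probes, whose ratios the offset shrinks towards 0. A small shift in share is therefore not excluded. Dye bias of the probe was not tested by its smallest value of 0.55, since the naming rule required 1 sign on all arrays; a constant bias cancels in the mean over the balanced orientations. Donor age and embryo stage stay open as untested. Donor age cannot be told apart from the time of collection, and the stage of the embryos within a pool was not analysed here. The only probe of the gene also did not pass the adjusted threshold. Another assay of NANOG in staged embryos with counted inner cell mass cells would be needed to test stage and inner cell mass share.

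Arrays of one dye orientation resembled each other at r = 0.58 and 0.28. Gene-specific dye bias as the whole cause would make unturned ratios correlate as much across orientations, but the highest such value was 0.182. A shared age difference as the whole cause would make turned ratios correlate as much across orientations. Over all tested probes those values were -0.18, -0.17, 0.14 and -0.07, which argues against it as the whole cause. The values are part of the resemblance itself, and a smaller share of age is not excluded by them. Noise near background is not excluded. Among the brightest 12149 probes, the upper tertile, replicates 1 and 2 correlated at 0.661, above their value over all probes. Replicates 3 and 4 correlated at 0.198, below their value over all probes. That was above the mean of -0.03 for the pairs of opposite orientation but below the highest of them, 0.214. The resemblance was thus weaker for replicates 3 and 4 there. Among the dimmest 12149 probes, replicates 1 and 2 correlated at 0.342 and replicates 3 and 4 at 0.463. Pairs of opposite orientation lay there between -0.281 and -0.198, with a mean of -0.25. The contrast between orientations in these pairs was thus larger among dim probes than among bright ones. A difference between the heifers of replicates 1 and 2 and those of replicates 3 and 4 cannot be told apart from the dyes, since the 513 probes past an adjusted p of 0.05 for the orientation term would be the same for both. Mixtures of these, among them pools at slightly different stages, stay open.

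Keeping or turning the sign of each array gives 8 patterns, counting mirror images once, which are too few for a share under 0.05. The 1.5-fold list held 501 probes in the real pattern, the only 1 of the 8 to reach that number, and at most 491 in the others, in the pattern that follows the dye orientation. That pattern gave more probes at an unadjusted p under 0.05 in limma, 5153 against 3448 in the real one. It also gave 1 sign on all 4 arrays in more probes, 24.95% against 16.7%. The real pattern gave 0 probes past an adjusted p of 0.05, a count that all 8 patterns reach by construction, so that nothing follows from it; the pattern that follows the dye orientation gave 6. With the dye term as a block the real count was still 0, with 595 probes in the 1.5-fold list. In camera 0 lists passed in the real pattern, which all 8 likewise reach by construction, and at most 1 in the others. Fry's mixed test called 2 lists in the real pattern and 17 in the one that follows the dyes, which points to a structure of the arrays along the dye orientation or the heifer pairs.

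Among the 65 genes at least 1.5-fold lower at an unadjusted p under 0.05, 5 are pseudogenes in the reference annotation, or 7.69%, against 189 of 13516 measured genes, or 1.40%; no test was made, since the count followed after 3 of the 5 had been noticed among the named genes. Among the 100 genes higher at the same limits, 1 is a pseudogene. The 5 are LOC509782, LOC513925, LOC100295855, LOC100294771 at -0.64 ± 0.38 and LOC782284 at -0.61 ± 0.22, each lower in all 4 heifers. Which transcripts their probes read was not analysed here.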
